A study of Candida albicans with 6 samples.

How the data were processed

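RNA sequencing libraries were analysed from 6 samples of Candida albicans SC5314, 3 treated with aureobasidin A (AbA) and 3 with DMSO, and each was placed in its group by the treatment given in its labels. Per the labels' protocols, cells from a 24 h preculture grew for 6 h in fresh YPD broth and were exposed to AbA at 1 µg/ml for 3 h. The same treatment text stands on the DMSO samples, and their solvent dose is not given. RNA was extracted with the RNeasy Mini kit and enriched before cDNA synthesis, per the labels' protocols, which do not say how it was enriched or whether strand was kept. Reads from overlapping or antisense genes may therefore be shared, and those from near-identical copies (histones, TLO genes) depend on counting settings not given in the sources used here.

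The deposited values were raw read counts per gene, whole numbers with no normalization. Per the submitters' processing notes, FastQC 0.11.8, STAR 2.7, featureCounts 2.0.0 and DESeq2 were used. The genome build and annotation were not given in the sources used here, so that no coordinates are printed. All 6245 gene identifiers matched the RefSeq gene table of assembly ASM18296v3 (3 after a coded comma was restored), which was used only for symbols and gene classes, and 2957 had a symbol. Total counts per library ranged from 19593394 to 26111920. No library pair agreed within counting noise, so that each was kept as a replicate.

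Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed with filterByExpr (minimum count 10, minimum total 15), which left 6066 genes and removed 179, of which 44 had no read in any library. Libraries were scaled with TMM factors, and AbA was compared with DMSO by the quasi-likelihood F test with Benjamini-Hochberg adjustment over the tested genes. An adjusted p under 0.05 counted as changed, and a limit of 2-fold was counted separately. The common biological coefficient of variation was 6.26%, and the fit had 4 residual degrees of freedom and 5.15 prior degrees of freedom. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. Levels are TMM-scaled CPM, given as mean ± SD over the 3 libraries of a group.

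Before the data were examined, 31 lists of pathway, stress, wall, morphology and switching genes were written from general knowledge, with 1091 symbols, of which 106 were not matched to a gene. Each list was compared with all other tested genes by camera of limma 3.58.1 with a preset correlation of 0.01, adjusted over the 31 lists. Members past the per-gene test were counted over all genes and with p-values adjusted over the list alone. Genes were named by a rule fixed at the same time, which covered AUR1, the 10 largest rises and the 10 largest falls among changed genes with a symbol, a mean of at least 10 CPM and no overlap between the groups, and in each list with at least 4 measured members the largest rise and the largest fall with a mean of at least 10 CPM (the 2 largest where only a single direction had any). The rule gave 71 genes. Other genes named in the text were chosen after their values were seen.

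Alternatives set beforehand were the RLE factors of DESeq2, library totals without factors, no filter, a filter at 10 CPM, DESeq2 1.42.0, limma-voom, robust dispersion, the replicate number as a block, an adjusted p under 0.01, each library left out in turn, and for lists an estimated correlation, fry and camera on ranks. Leaving out ribosomal RNA genes and shortening a pair of lists were added after the data were seen. The procedure was tested on simulated data for the AbA against DMSO comparison, with 6061 genes at the real means and depths and 200 of them changed. There edgeR recovered 68% of 1.25-fold, 88% of 1.5-fold and 100% of 2-fold and 4-fold changes, and 8 of its calls (4.30%) were false.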

Results

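Transcript levels were measured by RNA sequencing in 6 libraries of Candida albicans SC5314, a standard laboratory strain of this yeast that is also a human fungal pathogen. There were 3 libraries from cells given aureobasidin A (AbA), a cyclic depsipeptide antifungal that inhibits the inositol phosphorylceramide synthase Aur1, and 3 from cells given the solvent dimethyl sulfoxide (DMSO). The labels give a dose of 1 µg/ml and an exposure of 3 h in YPD medium. Reads assigned to genes came to 26111920, 24366258 and 24047764 in DMSO replicates 1 to 3 and to 19593394, 22374311 and 22768130 in AbA replicates 1 to 3. Ribosomal RNA genes held 2.33% of the reads of DMSO replicate 3 and between 0.331% and 0.481% of those of the other 5 libraries. The first principal component of log expression held 83.8% of the variance and separated the groups. DMSO replicates 1 to 3 had scores of -16.0, -16.2 and -18.2 on it, and AbA replicates 1 to 3 had scores of 19.1, 18.8 and 12.6, so that AbA replicate 3 lay nearest to the DMSO libraries. The labels do not say whether the replicates were separate cultures, and p-values then measure only the spread between these libraries, which may be technical.

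The design asked which transcripts differ between AbA-treated and DMSO-treated cells. With AbA, lists of drug efflux, sphingolipid synthesis and proteasome genes were higher, with the inositol synthesis gene INO1, and lists of ergosterol synthesis, wall remodelling and ribosomal protein genes were lower, with most histone genes and the phosphate transporter gene PHO89. These list calls were made with a preset correlation between genes, and all 6 were lost with an estimated correlation (camera adjusted p from 0.0843 to 0.715). AUR1, the gene of the AbA target, rose 1.47-fold (log2 fold change 0.55 ± 0.054, SE, 3 libraries per group), from 131 ± 6.56 to 193 ± 9.38 CPM (normalized read count scaled to library size, mean ± SD, n = 3), with an adjusted p of 4.89e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Among changed genes with a symbol and a mean of at least 10 CPM, the largest rise was that of RBR1, a GPI-anchored wall protein gene, which was 12.1-fold higher, and the largest fall that of PHO89, which was 12.5-fold lower. Of 6066 genes tested, 3452 (56.9%) changed, 1728 to higher and 1724 to lower levels, and most changes were small. The median fold was 1.26 among genes that rose and 1.25 among genes that fell. At least 2-fold changes were found for 223 genes, 156 higher and 67 lower, and at least 4-fold changes for 14 higher and 15 lower genes. All 3 AbA libraries lay on the same side of all 3 DMSO libraries for 3867 genes (63.7%, where chance gives 10%), and for 222 of the 223 genes past the 2-fold limit.

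The 10 largest rises were taken among changed genes with a symbol, a mean of at least 10 CPM and no overlap between the groups. They were those of RBR1, CDR2, INO1, IFD6, MDR1, ADH3, RTA3, INO2, GCA2 and PGA13. RBR1 rose from 93.7 ± 6.52 to 1134 ± 117 CPM (log2 fold change 3.60 ± 0.090, SE). CDR2, which encodes an ABC-type drug efflux pump, rose 7.78-fold, from 66.4 ± 1.61 to 517 ± 5.90 CPM (log2 fold change 2.96 ± 0.046). INO1, the gene of inositol-1-phosphate synthase, rose 7.53-fold, from 10.5 ± 2.25 to 79.8 ± 18.3 CPM (log2 fold change 2.91 ± 0.19), and INO2, a transcription factor gene, rose 3.30-fold, from 48.8 ± 2.93 to 161 ± 13.9 CPM. RTA3, which encodes a membrane protein of the lipid-translocating exporter family, rose 3.90-fold, from 228 ± 8.33 to 888 ± 54.1 CPM. The major facilitator drug pump gene MDR1 rose 4.56-fold (log2 fold change 2.19 ± 0.43), but its size rested on AbA replicate 3. The AbA libraries 1 to 3 had 23.6, 18.5 and 62.3 CPM of MDR1 against a DMSO mean of 7.66 ± 1.35, and without AbA replicate 3 the fold was 2.74. IFD6, of the aldo-keto reductase family, rose by 2.36 ± 0.18 on the log2 scale and ADH3, of the alcohol dehydrogenase family, by 2.01 ± 0.16. The glucoamylase gene GCA2 rose by 1.67 ± 0.11 and the wall protein gene PGA13 by 1.66 ± 0.12. The highest adjusted p among these 10 genes and the 10 with the largest fall was 0.00222, of MDR1, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

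**Figure D1:**
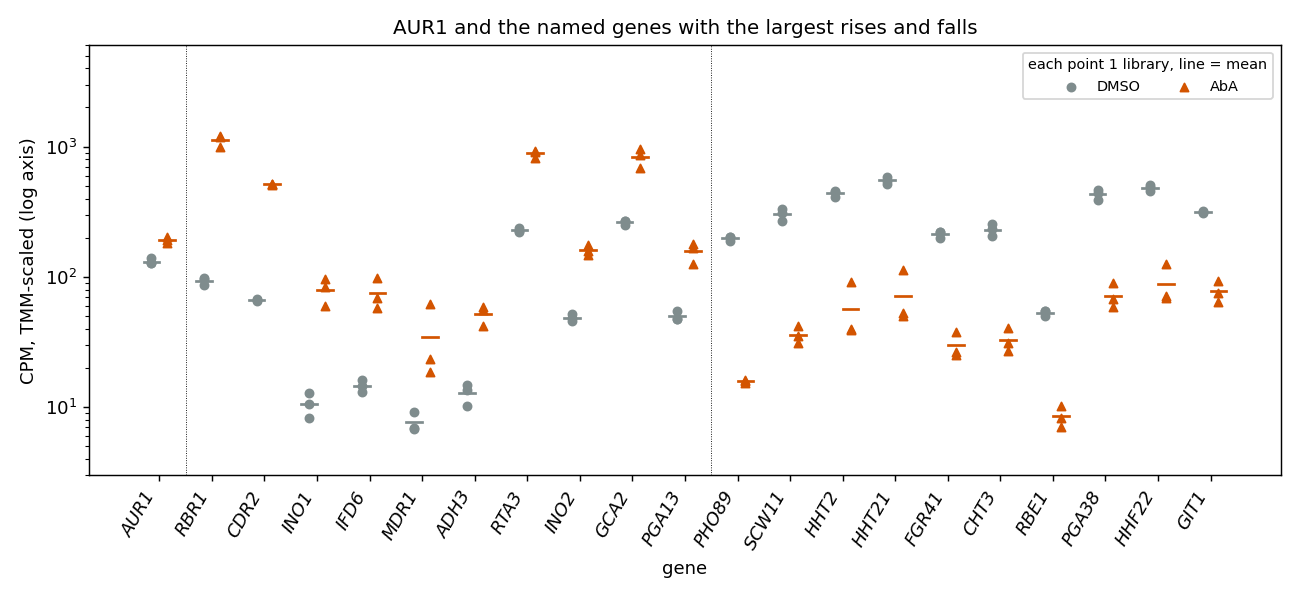
Normalized expression (TMM-scaled CPM, log axis) of AUR1 and of the 10 named genes with the largest rise and the 10 with the largest fall, with a point for each of the 3 DMSO and 3 AbA libraries and a line at each group mean. RBR1 averaged 1134 CPM with AbA and 93.7 CPM with DMSO, PHO89 averaged 15.9 and 198 CPM, and the point of AbA replicate 3 for MDR1 (62.3 CPM) lies apart from those of the other 2 AbA libraries.

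Under the same limits (a symbol, a mean of at least 10 CPM and no overlap between the groups), the 10 changed genes with the largest fall were as follows. They were PHO89, SCW11, HHT2, HHT21, FGR41, CHT3, RBE1, PGA38, HHF22 and GIT1. PHO89 fell from 198 ± 8.29 to 15.9 ± 0.460 CPM (log2 fold change -3.64 ± 0.056, SE, n = 3 per group). GIT1, the glycerophosphoinositol permease gene, was 4.06-fold lower, at 77.5 ± 14.8 against 315 ± 4.24 CPM. SCW11, which encodes a wall glucanase of daughter-cell separation, was 8.39-fold lower (36.0 ± 5.50 against 303 ± 32.5 CPM), and the chitinase gene CHT3, which acts at the same step, was 6.98-fold lower (32.9 ± 6.90 against 231 ± 23.8 CPM). The histone H3 genes HHT2 and HHT21 were 7.69-fold and 7.64-fold lower and the histone H4 gene HHF22 was 5.49-fold lower. HHT2 stood at 39.3, 39.9 and 92.0 CPM in AbA replicates 1 to 3 against a DMSO mean of 440 ± 23.9 CPM. Histone copies are nearly identical, so that the split of reads between them is uncertain. The remaining genes were FGR41 (log2 fold change -2.83 ± 0.13), the wall protein gene PGA38 (-2.59 ± 0.14) and RBE1 (-2.64 ± 0.11), whose protein is related to plant pathogenesis-related proteins.

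Of 31 gene lists fixed before the data were examined, 13 differed from the other genes tested by camera with a preset inter-gene correlation of 0.01, 6 to higher and 7 to lower levels. None of the 13 calls held with an estimated correlation, where 0 lists passed after adjustment and 5 had an unadjusted p under the threshold. For sphingolipid synthesis and drug efflux the estimate was 0.0131 and -0.00415, near or below the preset 0.01. A higher correlation therefore does not account for the loss in these lists. With an estimated correlation camera also uses only the 4 residual degrees of freedom of the fit, a limit that a preset correlation does not carry. Its power was thus low for every list, and a lost call is weak evidence against a list. For cytosolic ribosomal proteins the estimate was 0.936. A split of the libraries that mixed the groups also gave 13 lists with the preset correlation. Its groups held unequal numbers of AbA libraries, so that part of the AbA effect remained and the count is not one of chance alone. With fry, which asks whether a list moved one way on balance, 20 lists passed, 11 of these 13 and 9 of the other 18. The losses with fry were cytosolic ribosomal proteins (adjusted p = 0.0503) and ribosome biogenesis (0.124). The adjusted p-values of lists below are Benjamini-Hochberg values over the 31 lists.

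Sphingolipid synthesis genes were higher as a list. Of 22 tested members, 13 rose, 5 fell and 4 did not pass (18 changed when adjusted over the list alone), with a median log2 fold change of 0.38 (camera adjusted p = 3.47e-07, and adjusted p = 0.0843 with an estimated correlation). The largest rise was that of RTA3, and the ceramide synthase gene LAG1 rose by 1.28 ± 0.047 on the log2 scale, MIT1, of inositolphosphorylceramide mannosylation, by 1.35 ± 0.061, the sphingoid base kinase gene LCB4 by 0.74 ± 0.046 and the serine palmitoyltransferase subunit gene LCB2 by 0.38 ± 0.046. The desaturase gene SLD1 had the largest fall (-0.57 ± 0.071). RTA3, RTA2 and CSH1 do not encode sphingolipid enzymes, the first pair being of the lipid-translocating exporter family and CSH1 of the aldo-keto reductase family. Without these 3 genes, a choice made after the data were seen, 10 of 19 members rose and 5 fell, with a median of 0.34 and an adjusted p of 0.000605 by camera with the preset correlation. An estimated correlation, with which the full list lost its call, was not tried on the shortened list.

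Genes of drug efflux and its regulators were also higher as a list. The list also held RTA3, which the sphingolipid list shares, and IFD6, of the aldo-keto reductase family. A list without them was not tried. Of 26 members, 17 rose, 8 fell and 1 did not pass (25 adjusted over the list alone), with a median log2 fold change of 0.32 (camera adjusted p = 3.47e-07, and adjusted p = 0.0843 with an estimated correlation). The ABC transporter genes CDR1 and YOR1 rose by 1.32 ± 0.061 and 1.52 ± 0.051, and TAC1, the transcription factor gene that regulates CDR1 and CDR2, rose by 1.12 ± 0.045. CDR1 was the most abundant of these, at 3895 ± 113 CPM with AbA and 1562 ± 44.0 CPM with DMSO (n = 3). TPO4, a polyamine transporter family gene, fell by 0.93 on the log2 scale (SE 0.054). The camera test on ranks did not pass for this list (adjusted p = 0.0659).

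Proteasome genes rose by a small and even amount. All 27 members rose, also when adjusted over the list alone, with a median log2 fold change of 0.31 (camera adjusted p = 2.36e-06, and adjusted p = 0.569 with an estimated correlation). RPN4, the regulator of proteasome genes, rose by 0.63 ± 0.061 and the core subunit gene PRE6 by 0.42 ± 0.049. Genes of the TCA cycle and respiratory chain were higher too, with 32 of 51 members rising, 1 falling and 18 not passing (34 changed when adjusted over the list alone) and a median of 0.17 (camera adjusted p = 0.00738, and adjusted p = 0.709 with an estimated correlation). YMX6, an NADH dehydrogenase gene, rose by 0.78 ± 0.046, and the member that fell was the alternative oxidase gene AOX2 (-0.96 ± 0.11). Without DMSO replicate 2, 2 members fell.

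Fatty acid synthesis genes were higher in 8 of 13 members, lower in 1 and not past the test in 4 (9 changed when adjusted over the list alone), with a median log2 fold change of 0.24 (camera adjusted p = 0.0278, and adjusted p = 0.36 with an estimated correlation). SPT23, a transcription factor gene of fatty acid desaturation, rose by 0.81 ± 0.070. The desaturase gene FAD3 had the only fall (-0.48 ± 0.16), its libraries overlapped between the groups, and its call was lost with library totals (edgeR adjusted p = 0.0527) and without AbA replicate 1 (0.0886), AbA replicate 2 (0.0932), DMSO replicate 2 (0.116) or DMSO replicate 3 (0.064). White-opaque switching genes rose in 9 of 16 members, with 1 fall and 6 not past the test (10 changed when adjusted over the list alone) and a median of 0.27 (camera adjusted p = 0.0215, and adjusted p = 0.275 with an estimated correlation). The switching regulator genes WOR2 and WOR4 rose by 1.47 ± 0.086 and 0.61 ± 0.078. WOR1, the main switching regulator gene, had a log2 fold change of 0.01 ± 0.30 and did not pass. The member that fell was the pheromone receptor gene STE2 (-0.43 ± 0.14), a call lost without AbA replicate 1 (edgeR adjusted p = 0.079), DMSO replicate 2 (0.0583) or DMSO replicate 3 (0.0685).

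Among lists that were lower, 7 of 36 members of beta-glucan synthesis and wall remodelling rose, 18 fell and 11 did not pass (25 changed when adjusted over the list alone). The median log2 fold change was -0.14 and the mean -0.40 (camera adjusted p = 6.57e-07, and adjusted p = 0.275 with an estimated correlation). Besides SCW11 and RBE1, the endoglucanase gene ENG1 (-1.66 ± 0.064), the glucan synthesis gene SKN1 (-1.54 ± 0.056) and the glycosidase gene PHR1 (-1.52 ± 0.055) fell, while the glycosidase gene CRH12 rose by 0.47 ± 0.067. GSC1, the glucan synthase gene, had a log2 fold change of -0.04 ± 0.054 and did not pass. Without AbA replicate 2, 4 members rose in place of 7 and the median was -0.18. Without AbA replicate 3 the median was -0.09.

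The list of cell cycle, DNA replication and histone genes had 12 rises, 27 falls and 21 members not past the test among 60 (40 changed when adjusted over the list alone), with a median log2 fold change of -0.11 (camera adjusted p = 0.000476, and adjusted p = 0.709 with an estimated correlation). The histone genes HTA2 (-1.80 ± 0.12), HTA1 (-1.72 ± 0.14) and HTB1 (-1.38 ± 0.10) fell, as did the cyclin gene CLB2 (-0.96 ± 0.050). POL1, a DNA polymerase alpha subunit gene, had the largest rise (0.70 ± 0.075). The list median moved with single libraries, to -0.20 without AbA replicate 3 and -0.07 without AbA replicate 2. Without the histone genes, a choice made after the data were seen, the median was -0.01 and the call was lost (camera adjusted p = 0.173).

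Cytosolic ribosomal protein genes fell in 62 of 73 members, rose in 1 and did not pass in 10 (63 changed when adjusted over the list alone), with a median log2 fold change of -0.35 (camera adjusted p = 1.2e-06, and adjusted p = 0.715 with an estimated correlation). The acidic protein gene RPP2B had the largest fall (-0.85 ± 0.13), and RPP1B, the member that rose, had a log2 fold change of 0.21 ± 0.057. The list did not pass fry (adjusted p = 0.0503), and without AbA replicate 1, 2 members rose. Ribosome biogenesis genes fell in 38 of 76 members and rose in 0 by edgeR with TMM scaling (34 changed when adjusted over the list alone). Their median was -0.27 (camera adjusted p = 0.00109, and adjusted p = 0.715 with an estimated correlation, or 0.124 by fry). The count of rises was also 0 with DESeq2, limma-voom or at an unadjusted edgeR p under 0.05, where 44, 38 and 45 members fell. With scaling by library totals, 30 members fell and 1 rose. DBP2, an RNA helicase gene, fell by 0.68 on the log2 scale (SE 0.10) and the pre-ribosome factor gene NSA1 by 0.64 (SE 0.16). The count of falls in this list also moved with single libraries: it was 62 without AbA replicate 3, 24 without AbA replicate 1, AbA replicate 2 or DMSO replicate 3, and 21 without DMSO replicate 2.

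Ergosterol synthesis genes fell in 19 of 26 members, rose in 2 and did not pass in 5 (21 changed when adjusted over the list alone), with a median log2 fold change of -0.26 (camera adjusted p = 0.00145, and adjusted p = 0.709 with an estimated correlation). The sterol methyl oxidase gene ERG251 fell by 1.23 on the log2 scale (SE 0.086), the desaturase gene ERG3 by 0.96 (SE 0.12), the squalene epoxidase gene ERG1 by 0.87 (SE 0.12) and ERG11, the gene of the azole target, by 0.60 (SE 0.080). UPC2, the transcription factor gene of this pathway, rose by 0.40 ± 0.058. Without DMSO replicate 1 or DMSO replicate 3, 1 member rose.

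Hypha-associated genes rose in 10 of 30 members, fell in 12 and did not pass in 8 (23 changed when adjusted over the list alone), with a median log2 fold change of -0.17 (camera adjusted p = 0.022, and adjusted p = 0.569 with an estimated correlation, or 0.274 by camera on ranks). The hyphal wall protein gene HWP1 fell by 1.10 on the log2 scale (SE 0.092) and FGR41 had the largest fall, while FAV2 rose by 1.29 ± 0.083. Without AbA replicate 2, 6 members rose in place of 10. Genes of amino acid, ammonium and oligopeptide uptake rose in 10 of 36 members, fell in 16 and did not pass in 10 (26 changed when adjusted over the list alone). Their mean log2 fold change was -0.18 and their median -0.03, which became 0.01 with scaling by library totals (camera adjusted p = 0.0263, and adjusted p = 0.275 with an estimated correlation, or 0.247 by camera on ranks). The median was -0.059 without AbA replicate 1 and -0.015 without AbA replicate 3. The oligopeptide transporter gene OPT4 fell by 1.99 on the log2 scale (SE 0.092) and the amino acid permease gene GAP1 by 1.26 (SE 0.093), while OPT7 rose by 0.56 ± 0.080.

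**Figure D2:**
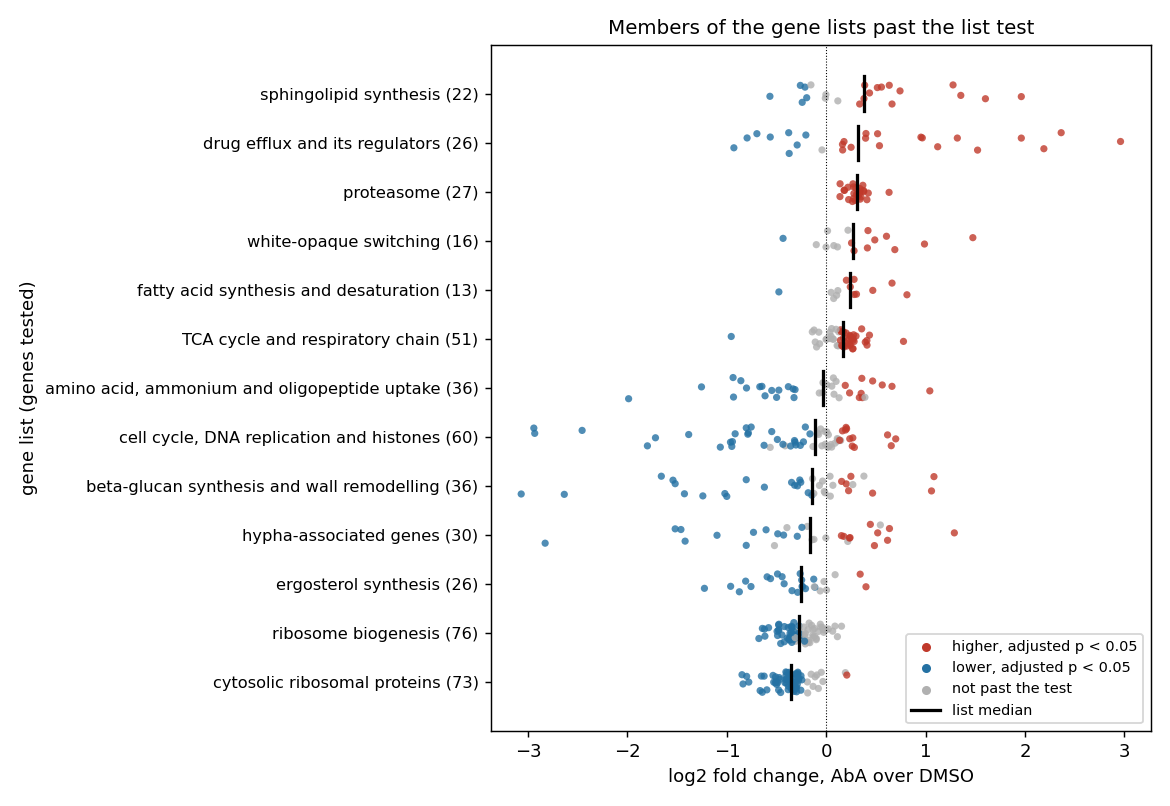
Log2 fold change (AbA minus DMSO) of each tested member of the 13 gene lists that passed camera, with red points for genes that rose, blue points for genes that fell, grey points for genes not past the test and a black bar at each list's median. All 27 proteasome points lie above 0 around a median of 0.31, and the sphingolipid points have a median of 0.38.

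The other 18 lists did not pass camera with the preset correlation, though many of their members changed. Of all genes tested 56.9% changed, so that a count of changed members is not by itself a trait of a list. By camera on ranks 3 of them passed, autophagy (adjusted p = 0.0161), gluconeogenesis (0.0388) and amino acid synthesis (0.0473). In phospholipid and inositol metabolism, 7 of 29 members rose and 12 fell (19 changed adjusted over the list alone), among them INO1 and INO2 among the rises and GIT1 among the falls (camera adjusted p = 0.283). ITR1, an inositol transporter gene, rose by 0.74 ± 0.094. Of the genes of cell wall integrity, calcineurin and osmotic signalling, 4 of 38 rose and 14 fell (18 adjusted over the list alone; camera adjusted p = 0.196), and without AbA replicate 3, 7 rose. The zinc-finger factor gene CRZ2 rose by 1.07 ± 0.080 and the sodium pump gene ENA21 fell by 1.35 on the log2 scale (SE 0.071). In chitin synthesis and breakdown, 2 of 17 rose and 5 fell (7 adjusted over the list alone; camera adjusted p = 0.429), with a rise of the chitin deacetylase gene CDA2 by 1.44 ± 0.083. Adhesins and GPI-anchored wall proteins split into 20 rises, RBR1 the largest, and 17 falls among 59 (37 adjusted over the list alone; camera adjusted p = 0.467). For yeast-form genes, 4 of 13 rose and 4 fell (8 adjusted over the list alone; camera adjusted p = 0.32), PGA13 and SCW11 being the extremes. In ER folding and glycosylation, 7 of 39 rose and 9 fell, or 9 rose and 6 fell with library totals (15 adjusted over the list alone; camera adjusted p = 0.297). The disulfide isomerase gene PDI1 rose by 0.43 ± 0.053 and the mannosyltransferase gene MNN1 fell by 1.22 (SE 0.044), and without AbA replicate 2, 4 members rose.

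Carbon metabolism lists went both ways. In glycolysis and fermentation, 5 of 22 rose and 12 fell (17 adjusted over the list alone; camera adjusted p = 0.201), with GAL4 up by 0.54 ± 0.097 and the hexokinase gene HXK2 at a log2 fold change of -0.65 ± 0.064. Hexose transporter genes had 5 rises and 7 falls among 19 (13 adjusted over the list alone; camera adjusted p = 0.358). Their median was 0.04 (-0.05 without AbA replicate 1) while their mean was -0.09, and HGT20 rose by 0.52 ± 0.071 while HGT1 fell by 0.97 (SE 0.068). Of the gluconeogenesis, glyoxylate and beta-oxidation genes, 19 of 40 rose and 6 fell (26 adjusted over the list alone; camera adjusted p = 0.0749). This list passed by camera on ranks (adjusted p = 0.0388) and without AbA replicate 3 (0.0139) or DMSO replicate 2 (0.0302), and without DMSO replicate 1 only 3 members fell. FAA2-3, of the acyl-CoA synthetase family, rose by 1.02 ± 0.096, and ATO1 fell by 0.41 (SE 0.12), a call lost without DMSO replicate 1 (edgeR adjusted p = 0.0557). Trehalose and glycogen genes had 3 rises and 6 falls among 14 (9 adjusted over the list alone; camera adjusted p = 0.346). GAC1 rose by 0.63 ± 0.13 and TPS3 fell by 0.66 (SE 0.074), and without AbA replicate 3 or with library totals, 5 members rose.

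For amino acid synthesis, 8 of 64 members rose and 25 fell (32 adjusted over the list alone; camera adjusted p = 0.126, or 0.0473 on ranks), LEU4 rising by 0.89 ± 0.12 and THR1 falling by 0.63 (log2 fold change -0.63 ± 0.070). Sulfur assimilation and methionine genes had 8 rises and 3 falls among 23 (10 adjusted over the list alone; camera adjusted p = 0.452). MET4, a transcription factor gene, rose by 0.66 ± 0.059 and SAM4 fell by 0.61 (SE 0.072). The count of falls in this list was 1 without AbA replicate 1, AbA replicate 2 or DMSO replicate 3, 2 without DMSO replicate 2 and 7 without AbA replicate 3, and that of rises was 4 without DMSO replicate 3 and 5 without DMSO replicate 2. Autophagy and vacuolar protease genes rose in 8 of 12 members and fell in 0 by edgeR, DESeq2, limma-voom or at an unadjusted edgeR p under 0.05 (8 adjusted over the list alone; camera adjusted p = 0.0661), with the protease gene PRB1 and ATG9 both up by 0.47 (SE 0.053 and 0.065). The list passed by camera on ranks (adjusted p = 0.0161), with library totals (0.0474) and without AbA replicate 3 (0.016), and 4 members rose without AbA replicate 2.

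Heat shock and chaperone genes rose in 5 of 27 members and fell in 11 (16 adjusted over the list alone; camera adjusted p = 0.173). The disaggregase gene HSP104 fell by 0.92 (SE 0.062) and HSP31 had a log2 fold change of -1.12 ± 0.29, while ASR1 rose by 0.77 ± 0.076, and HSP90 had a log2 fold change of -0.07 ± 0.045, not past the test. In oxidative stress defence, 15 of 41 rose and 11 fell (27 adjusted over the list alone; camera adjusted p = 0.887), from the glutathione S-transferase family gene GTT13 (1.24 ± 0.093) to the superoxide dismutase gene SOD5 (-1.46 ± 0.083). Iron and copper acquisition had 13 rises and 15 falls among 41, or 14 and 13 with library totals (29 adjusted over the list alone; camera adjusted p = 0.467), with the siderophore transporter gene SIT1 falling from 154 ± 15.5 to 38.3 ± 19.6 CPM and the ferric reductase family gene FRE3 rising by 0.49 ± 0.055 on the log2 scale. For zinc acquisition, 2 of 4 rose and 1 fell (3 adjusted over the list alone; camera adjusted p = 0.283). The zinc transporter gene ZRT1 rose by 1.44 ± 0.11 and ZRT2 fell by 0.47 (SE 0.098), and without AbA replicate 2, 2 members fell. Secreted hydrolase genes rose in 13 of 26 members and fell in 3 (16 adjusted over the list alone; camera adjusted p = 0.201), with the lipase gene LIP7 up by 0.73 ± 0.099 and the aspartyl protease gene SAP9 at -0.82 ± 0.047.

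The number of genes past the test rested on 3 libraries per group, for which edgeR recovered 68% of simulated 1.25-fold changes and 100% of 2-fold changes. In that simulation 200 of 6061 genes changed, a smaller share than in the data. Its adjusted threshold was thus stricter, and 68% may understate recovery in the data. The number of 2-fold changes depended on the filter on low counts and was 143 where a mean of at least 10 CPM was required.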

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

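Leaving out ribosomal RNA genes and shortening the sphingolipid and cell cycle lists were chosen after the data were seen, and the other alternatives beforehand. The count of 3452 changed genes ranged from 3273 to 3460 over other scalings, filters, tests and dispersion settings, and was 2466 at an adjusted p under 0.01. Without 1 library at a time it ranged from 2798 to 3768 (1407 to 1865 higher, 1391 to 1903 lower), and the count of 2-fold changes ranged from 207 to 260 (139 to 171 higher, 64 to 89 lower). Requiring a mean of 10 CPM left 143 genes changed at least 2-fold in place of 223 and 85 higher in place of 156, since that filter tests 5657 genes in place of 6066 and removes weakly expressed ones. The near-even split of 1728 higher and 1724 lower genes turned with the setting, to 2048 and 1386 with library totals, 1698 and 1744 with RLE factors and 1676 and 1756 with DESeq2. No call of a named gene or of a list reversed its direction. List medians near 0 did change sign: with library totals those of amino acid uptake (-0.03 to 0.01), chitin (-0.01 to 0.04) and wall integrity signalling (-0.04 to 0.01), without AbA replicate 1 that of hexose transporters (0.04 to -0.05), without DMSO replicate 1 those of oxidative stress (0.02 to -0.01) and chitin (to 0.01), and without AbA replicate 3 that of chitin (to 0.02). All alternatives run on single genes at the main threshold kept the call of 118 of the 122 named genes, and of 1826 such checks 1814 kept it. The exceptions were FAD3 (lost with library totals at an edgeR adjusted p of 0.0527 and without each of 4 libraries), ATO1, HHT1 and STE2. Most named genes were chosen because they had changed in these libraries, so that keeping their calls was largely fixed in advance. Over all genes, 2769 to 3333 of the 3452 changed genes were also past the test without 1 library at a time. Of the gene list calls, 432 of 467 checks were kept. The number of lists past the test was 0 with an estimated correlation and 20 with fry, in place of 13, and 13 to 15 without 1 library at a time. With an estimated correlation camera uses only the 4 residual degrees of freedom of the fit, so that its power was low for every list. How far this accounts for the lost calls was not tested. The estimated correlation of sphingolipid synthesis (0.0131) and drug efflux (-0.00415) was near or below the preset 0.01, so that a higher correlation was not the cause there. The replicate numbers were not shown to pair the samples: deviations of same-numbered libraries had correlations across genes of 0.12, 0.04 and -0.08. AbA replicates 1 and 2 correlated best with the DMSO replicate of their own number, and AbA replicate 3 with DMSO replicate 2. With the replicate number as a block, 3341 genes changed, 223 of them at least 2-fold, and 13 lists passed. At these depths 1.25-fold changes were recovered in 68% of simulated cases, so that genes not past the test may hold changes of that size. The simulation changed 200 of 6061 genes, a smaller share than in the data. Its adjusted threshold was thus stricter, and 68% may understate recovery in the data.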

Other observations

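The families, the phosphate, pH, histone and library tests and their gene lists were chosen after the results they follow had been seen, and the tests of read sharing between histone copies, of a smaller share of cells in S phase and of the phosphate list by camera after their own values had been seen as well. Of 47 gene families with a shared symbol stem and at least 8 tested members, 14 passed camera with the preset correlation, but none of them did with an estimated correlation, where the lowest Benjamini-Hochberg adjusted p was 0.457 (PHO, LIP and MNN). All 9 ADE genes, of purine synthesis, fell with AbA (median log2 fold change -0.32), as did 9 of 10 MRPL genes of the mitochondrial ribosome (-0.28) and 8 of 12 TIM genes of mitochondrial protein import (-0.27), while all 12 ATP genes rose (0.28). In the TLO family of subtelomeric genes 10 of 11 rose (median 0.36), among them TLO1 by 0.90 ± 0.083 (SE, n = 3 per group), and whether its near-identical copies share reads was not tested, so that these cannot be counted as 10 independent rises. In the LIP family of secreted lipases 8 of 10 rose (median 0.69). In the MNN family of mannosyltransferases 9 of 16 fell and 1 rose. Of the HSP genes 7 of 9 fell and 0 rose (median -0.41), though the longer list of heat shock and chaperone genes did not pass camera.

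GCA1, a glucoamylase gene like GCA2, rose by 1.53 ± 0.080. The MRV family split, with MRV8 higher by 1.60 ± 0.092 and MRV2 and MRV3 at log2 fold changes of -2.49 ± 0.16 and -2.12 ± 0.20, both at under 10 CPM in each group. Of the 156 genes higher by at least 2-fold, 59 had a symbol, against 54 of the 67 lower ones. The genes without a symbol with the largest changes at a mean of 10 CPM or more were CAALFM_C603600CA (log2 fold change 3.68 ± 0.17) and CAALFM_C104010CA (3.00 ± 0.064) among the rises and CAALFM_C111990WA (-3.43 ± 0.14) and CAALFM_C104180WA (-1.83 ± 0.13) among the falls. Median log2 fold changes of the 8 chromosomes lay between -0.03 and 0.02.

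AbA replicate 3 lay nearer to the DMSO libraries than the other 2 AbA libraries, and over 174 genes past the 2-fold limit without it and with a mean of at least 10 CPM, it kept a median 0.819 of the CPM difference from DMSO, against 1.046 over 131 genes and 1.064 over 134 genes chosen in the same way for AbA replicates 1 and 2. DMSO RNA mixed into this library would lower rising and falling genes by a single share, but the share kept by rising genes was lower than that of falling genes (difference -0.0738, bootstrap 95% interval -0.108 to -0.00985), which argues weakly against mixing as the whole cause. The bootstrap drew genes of 1 library as if they were independent, so that correlation between genes may make this interval too narrow. Scaling and ribosomal RNA content were argued against as well, since the kept share reached at most 0.826 with RLE factors, library totals or ribosomal RNA genes left out. MDR1 was highest in this library. No biological explanation was tested, and a weaker or later response of these cells stays open as a hypothesis.

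Histone and daughter-cell separation genes (HHT2, HHT21, HHF22, HHF1, HTA1, HTA2, HTB1, SCW11, CHT3, ENG1, DSE1) were lower with AbA, while the H3-family gene HHT1 had a log2 fold change of 0.16 ± 0.048, a call lost without AbA replicate 1 (edgeR adjusted p = 0.055), DMSO replicate 2 (0.0675) or DMSO replicate 3 (0.064). Reads that only moved between near-identical copies would leave their sum unchanged and were argued against as the whole cause, because the summed counts had log2 fold changes of -1.0 ± 0.072 (SE) for HHT1, HHT2 and HHT21, -1.77 ± 0.13 for HTA1 and HTA2, and -1.51 ± 0.098 for HHF1 and HHF22. No fall rested on a single library, since the weakest log2 fold change over the 6 fits without 1 library each was -1.02. The genes were chosen as lower, and HHT2, HHT21, HHF22, SCW11 and CHT3 also for no overlap between the groups. This outcome was therefore largely fixed in advance. A smaller share of cells in S phase may underlie the pattern but cannot be told apart from other causes: the 17 DNA replication genes had a median of 0.117 with 7 rises and 1 fall, while the 16 genes of mitosis and the septum had a median of -0.12 with 2 rises and 8 falls, among them CDC5 (-0.94 ± 0.064). Replication genes are transcribed before S phase, so that their level does not count cells in it.

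PHO89, GIT1 and PHO84 (log2 fold change -2.01 ± 0.068), the sodium pump gene ENA21 and the alkaline-induced PHR1 were lower with AbA, and RBR1, which the pH regulator Rim101 represses, was higher. A lower pH of the AbA cultures could give this and stays open. PHR2, expressed at acid pH, had a log2 fold change of 0.0405 (SE 0.056, not past the test), and RIM8 rose by 0.36 ± 0.062. Of 5 further alkaline-induced genes, RIM101 (-0.26), ENA2 (-0.73), FRP1 (-0.37) and CTR1 (-1.15) fell while PRA1 rose (0.74). All of these but RIM101 were members of gene lists tested earlier, so that they are not fresh evidence. More phosphate available to AbA cells is a candidate explanation: 12 further phosphate-responsive genes had a median of -0.352, at percentile 0.03 of 10000 random lists matched on expression, which take no account of correlation between genes, and by camera in the edgeR fit their p was 0.0024 with the preset correlation but 0.162 with an estimated correlation. Of these, 7 fell, among them GIT2 (-1.17) and PHO87 (-0.80), and 3 rose, among them the phosphatase gene PHO8 (0.75). GIT2, GIT3 and GIT4 were members of a gene list tested earlier. Neither pH nor phosphate is given in the labels, and the treatment itself acting on these genes stays an untested alternative.

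The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 3452 changed genes by edgeR and the highest of the others 0 (1 of 10 splits reached the real count), with at most 222 genes at an unadjusted p under the threshold and at most 1 by DESeq2. For 2-fold changes the real split gave 223 and the highest other 0 (again 1 of 10 splits). Every other split held AbA libraries in both groups, so that the AbA effect itself widened the spread within groups. Gene counts near 0 in these splits were thus likely in advance and say little about the real split. For gene lists the real split gave 13 and the highest other also 13 (2 of 10 splits), in the split that put DMSO replicates 1 and 3 with AbA replicate 2. That split left unequal numbers of AbA libraries in its groups, so that part of the AbA effect stayed in the contrast. Its count of lists past camera with a preset correlation therefore cannot decide whether the list calls depended on the treatment.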
